A study of Sus scrofa with 12 samples.

How the data were processed

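Uterus from 12 crossbred gilts was profiled by poly(A) mRNA sequencing, with 1 library per animal. Per the labels, the animals formed 6 pairs of littermates, each with 1 gilt of low and 1 gilt of high iCrit ratio on the day of birth. The labels give collection at 14 days after birth for 4 litters and at 15 days for 2 litters, and littermates were collected at the same age. Litters are numbered 1 to 6, and litters 4 and 5 are those collected at day 15. Per the labels' protocols, libraries were stranded and sequenced as paired ends. Whether the counting used strand, which genome build was aligned to and which annotation was counted are not given in the sources used here. The submitters' processing notes name FastQC 11.5, Trimmomatic 0.36, TopHat2 2.1.1, Cufflinks, bedtools, DESeq2 and edgeR, without roles.

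The authors deposited a single table with 3 values per library, and each was examined before use. Per the file headers, the first block carries transcript IDs, and its values behaved as a count signal divided by one factor per library, the deposited signal being whole reads after multiplication by that factor. With a tolerance of 0.001 reads, 100% of these values came out whole. The second block is headed RPKM in the deposited table, but each column summed to between 999939 and 1000092 and its values equalled CPM of the third block, with 95% of the ratios between 0.998 and 1.00 over 11479 rows that had more than 50 counts in every library. It was therefore treated as CPM, without a length correction. The third block holds the deposited raw counts, which are estimated counts since 10.8% of the values were not whole, and these were rounded to whole reads for the tests. The features are transcripts, so reads shared between isoforms, paralogs or overlapping transcripts leave single transcript values uncertain.

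The table has 22898 rows, of which 19407 carry an ID and the signal values. The IDs were not on the rows of matching raw counts, apart from 16 rows where the raw counts equalled the reads recovered from the signal: across rows, the Spearman rho between the mean signal and the mean raw count on the same row was 0.033. Counts were joined to IDs by content. The whole reads recovered from the signal block equalled the rounded raw counts of at least 1 row for each of the 19407 IDs and of exactly 1 row for 18604 IDs. The other 803 had counts matching several rows and stayed without an ID. All 14821 transcripts kept by the main filter had a unique match. The IDs were taken to belong with the signal block because they fill the same 19407 rows. A check on neighbouring IDs did not settle this alone. Among windows of 40 consecutive ID numbers with at least 10 IDs, the highest median was 27808 for the signal, against at most 6346 in 200 shuffles, and 8567 for the raw counts on the same rows, against at most 6934, so that both exceeded every shuffle.

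None of the IDs was paired with a gene in the tables used. The IDs are transcript IDs, 0 of them were found in the table of gene names and 0 in the RefSeq table, and the deposited table does not pair them with genes. The 40 gene lists fixed before the data were examined, with cell type and pathway genes, therefore had 0 tested members, and no list test, neither camera nor fry, was run. The rule for named genes, also fixed in advance, took the 10 largest changes in each direction among genes with a symbol, an adjusted p under 0.05, the same direction in at least 5 litters and at least 1 CPM in the higher group. Where fewer than 3 passed it took the 5 smallest p in that direction, and it added up to 4 changed members of each list and a set of fixed genes. With no symbols the rule named 0 genes. In its place, the 2 transcripts with the smallest p in each direction are given by ID.

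Low and high libraries were compared with the quasi-likelihood test of edgeR 4.0.16 with robust estimation in R 4.3.3. TMM factors were used, low counts were removed by filterByExpr on the group, and p-values were adjusted by Benjamini-Hochberg at 5%. Litter entered as an additive block, since the series design states that the pairs came from the same litters. Log-CPM values used a prior count of 2. The pairing was also checked in the data: the correlation of littermates' deviations from their group means averaged 0.271, against -0.052 for low and high libraries of different litters, and was 0.374, 0.271, 0.021, 0.529, 0.332 and 0.097 in litters 1 to 6. The -0.052 is tied to the 0.271, because deviations cancel within each group. Standard errors of log2 fold changes were obtained from the quasi-likelihood F statistic, and 95% intervals from its degrees of freedom. Dependence on age was tested as the interaction of group and day with the litter block, and variation between litters by a test of the litter terms. Single transcripts were also given a two-sided exact permutation test that exchanged low and high within litters.

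Alternatives used DESeq2 1.42.0, limma 3.58.1 with voom or with a trend on the deposited CPM plus a pseudocount of 1 or 0.1, other normalizations, other low-count filters, a fit without the litter block, the day 14 litters alone, a 10% threshold and the removal of each litter in turn. Tables were read with Python 3.11.15. The fits were tested on simulated data, in which counts for 14821 transcripts were drawn from the real means, library sizes and dispersions with 200 of them changed. For low versus high, the edgeR test recovered 31.3% of 67 transcripts changed 1.5-fold, 83.6% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, and it called 8 unchanged transcripts. On the same counts DESeq2 recovered 46.3%, 85.1% and 95.5% and called 24 unchanged transcripts. For the difference between days the edgeR test recovered 0 of 67, 10.4% of 67 and 83.3% of 66 at these sizes. Each transcript was drawn independently and no library was made to stand apart, so recovery in the real libraries may differ. For low versus high in edgeR, 4.69% of unchanged simulated transcripts had an unadjusted p under 0.05, against 1.52% of the real transcripts.

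Depth ranged from 20809072 to 48306794 counted reads per library. The median standard error of a log2 fold change was 0.17, and this covers the spread between animals as well as counting error.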

Results

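Transcript levels were measured in the uterus of 12 neonatal gilts, 6 with a low and 6 with a high iCrit ratio. The iCrit, or immunocrit, is a serum measure taken in newborn piglets as an index of colostrum intake, and the labels describe the low gilts as having insufficient lactocrine exposure, that is, exposure to factors delivered in first milk. Each low gilt had a high littermate, which gave 6 pairs from 6 litters. Animals of 4 litters were 14 days old at collection and those of litters 4 and 5 were 15 days old. In litters 1 to 6, the low libraries held 32743239, 21175993, 22532040, 32887299, 33242880 and 20809072 counted reads, and those of their high littermates 35713135, 23876879, 27751966, 45297085, 48306794 and 23857065. The high library was thus the deeper in every litter, so depth was aligned with the iCrit group. Between 16482 and 18418 features had at least 1 read.

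The main variation among libraries did not follow the iCrit group. The first principal component of log-CPM held 28.3% of the variance and the second 19.9%. Low and high libraries were interspersed on both, while the low library of litter 3 lay apart from the others at -66.3 and -48.2. Littermates resembled each other: for 8 of 12 libraries, the library with the most similar deviations from its group mean was the littermate, and this held for both animals of litters 1, 2, 4 and 5. Deviations cancel within a group, which lowers the correlations inside it. This count therefore leans towards the other group, where the littermate is, and no chance value was computed for it. The mean correlation of littermates' deviations across transcripts was 0.271, and 2 of the 720 possible pairings of low with high libraries, the real one included, gave a mean as high (exact permutation p = 0.00278, one-sided). The other pairing, with a mean of 0.279, exchanged the low libraries of litters 1 and 3. Averaged over transcripts, low versus high accounted for 4.94% of the variance, where the 32 exchanges of low and high within litters averaged 7.20%. Without litter 3 it accounted for 9.85%, where the 16 exchanges averaged 8.07% and 2 of them, the real one included, gave as much (exact permutation p = 0.125, one-sided); so few exchanges cannot give a p under 0.05.

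**Figure D1:**
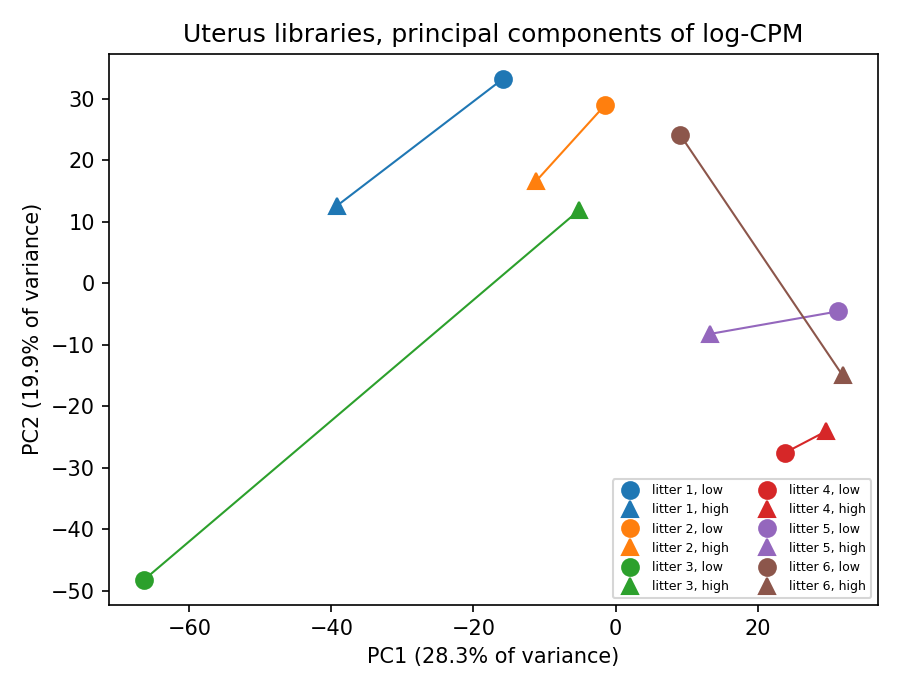
Principal components of log-CPM over 14821 transcripts, with PC1 on the x axis (28.3% of variance) and PC2 on the y axis (19.9%). Each point is 1 library, circles are low and triangles high gilts, colours are litters and lines join littermates. The low library of litter 3 sits at -66.3 on PC1 and -48.2 on PC2.

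The first comparison asked whether the uterine transcriptome of low gilts differed from that of their high littermates. Of 14821 transcripts tested with the litter block, 0 were changed at an adjusted p under 0.05 in the edgeR quasi-likelihood test, 0 higher and 0 lower in low gilts, and the smallest adjusted p was 1.00. At an unadjusted p under 0.05 there were 225 transcripts, 98 higher and 127 lower in low gilts, where 741 would be expected by chance. The shortfall was also seen with the litter block in limma-voom, at 251, and in DESeq2, at 264. It was not seen when limma-voom used quality weights per library, which gave 837. In edgeR, exchanges of low and high within litters gave 183 to 2126, so counts under 741 also arose with exchanged labels. With the litter block, limma-voom called 0 and DESeq2 called 2, both lower in low gilts. On simulated counts DESeq2 called 24 unchanged transcripts where edgeR called 8, and it recovered 46.3% of the 1.5-fold changes where edgeR recovered 31.3%. Those counts held no outlying library and do not give the rate of false calls in the real libraries. Without the block edgeR also called 0. Differences were small for most transcripts. The median absolute log2 fold change was 0.10 and 46 transcripts exceeded 1. For 89.9% of the transcripts the 95% interval of the fold change lay within 2-fold in either direction, and for 68.0% it lay within 1.5-fold. The same direction in all 6 litters was seen for 255 transcripts, 128 higher and 127 lower in low gilts, or 1.72% against the 3.13% that chance gives. Without litter 3 the comparison with chance turned, with 1244 of 14920 transcripts, or 8.34%, in the same direction in all 5 litters against the 6.25% that chance gives. Of the 16 exchanges of low and high within these litters, 3, the real one included, gave as many. The excess over 6.25% is therefore no evidence of a difference between low and high gilts.

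Of the transcripts with lower values in low gilts, ENSSSCT00000047075 had the smallest p. Its level was 1.88 ± 1.40 CPM (SD, n = 6) in low and 4.94 ± 1.41 CPM (SD, n = 6) in high gilts, and it was lower in the low gilt of 6 of 6 litters. The log2 fold change was -1.57 with a standard error of 0.28, the unadjusted p was 7.08e-05 and the adjusted p in edgeR was 1.00. The two-sided exact permutation test within litters gave p = 0.0313, the smallest value that 6 pairs allow. All 255 transcripts with 1 direction in 6 of 6 litters reach this value, and this one was selected for its small p. The exact p therefore adds no support, and the same selection applies to the other transcripts named below. DESeq2 with the litter block called this transcript, with a log2 fold change of -1.57 and an adjusted p of 0.000444.

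ENSSSCT00000054731, the other transcript called by DESeq2, had 0.260 ± 0.114 CPM (SD, n = 6) in low and 2.30 ± 2.93 CPM (SD, n = 6) in high gilts and was lower in the low gilt of 5 of 6 litters. The log2 fold change was -2.52 with a standard error of 0.53 and an adjusted p of 1.00 in edgeR, against -2.43 and an adjusted p of 0.0186 in DESeq2. The exact permutation p was 0.0625. It rested on few reads, between 2 and 13 per low library. The highest levels were 7.79 CPM in the high gilt of litter 6 and 3.42 CPM in that of litter 5, and the high gilt of litter 2 had 0.162 CPM.

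Among transcripts with higher values in low gilts, ENSSSCT00000071792 measured 7.72 ± 3.19 CPM (SD, n = 6) in low and 4.44 ± 1.30 CPM (SD, n = 6) in high gilts. The log2 fold change was 0.73 with a standard error of 0.20, low was higher in 5 of 6 litters, and the adjusted p was 1.00 in edgeR. ENSSSCT00000087297 measured 1.03 ± 1.23 CPM in low and 0.485 ± 0.726 CPM in high gilts (SD, n = 6). Low was higher in 6 of 6 litters, with a log2 fold change of 1.22, a standard error of 0.35 and an adjusted p of 1.00 in edgeR. Outside litter 4 this transcript rested on few reads, 3 to 8 per high library and 7 to 27 per low library. Its level differed more between litters than within them: both gilts of litter 4, at 3.43 CPM in the low and 1.96 CPM in the high animal, exceeded every other library, of which the highest had 1.19 CPM. The exact permutation p was 0.0625 for ENSSSCT00000071792 and 0.0313 for ENSSSCT00000087297. DESeq2 called neither of them. No gene name was paired with any of these IDs, and each ID is that of the deposited row whose normalised values match the counts.

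**Figure D2:**
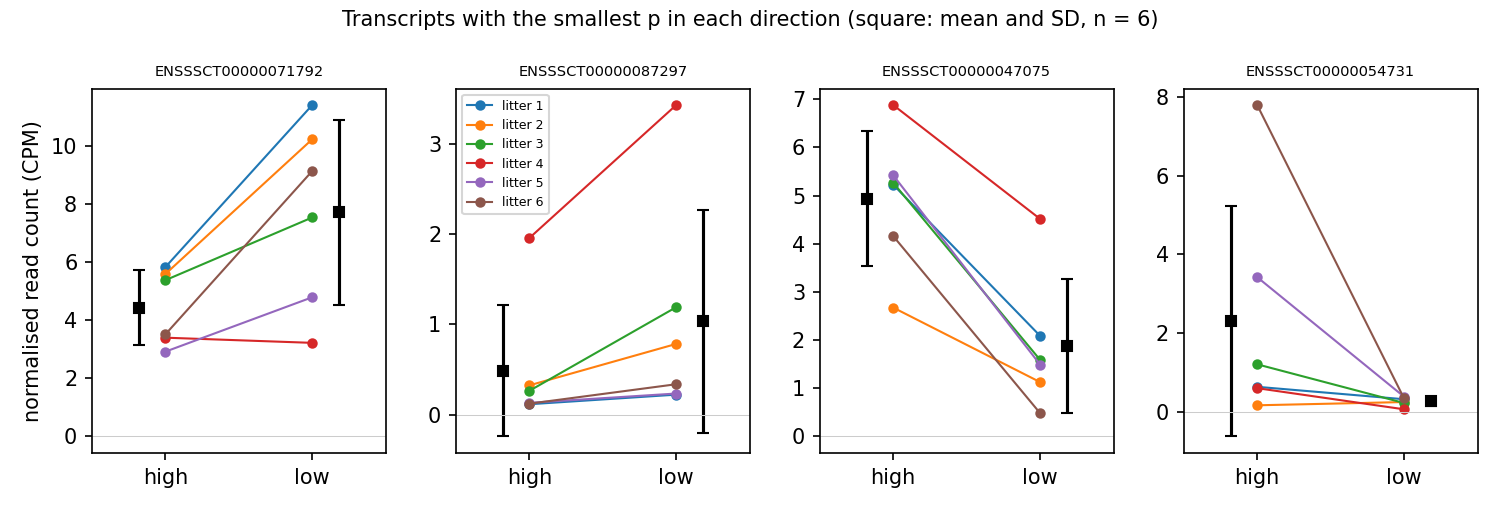
Normalised read count in CPM (y axis, linear) in high and low gilts (x axis) for the 2 transcripts with the smallest p in each direction. Coloured points are single libraries with lines joining the 6 pairs of littermates, and black squares with bars are the group mean and SD. ENSSSCT00000047075 was lower in the low gilt of 6 of 6 litters, and both gilts of litter 4 had the highest values of ENSSSCT00000087297.

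The number of small p-values depended on litter 3. With its 2 libraries left out, 1126 of 14920 transcripts had an unadjusted p under 0.05, or 7.55%, where 746 would be expected by chance, and 678 of them were higher and 448 lower in low gilts. The number called stayed at 0, with a smallest adjusted p of 0.240 in edgeR, and the median standard error was 0.14 in place of 0.17. Leaving out any other litter gave 178 to 248 transcripts at an unadjusted p under 0.05 and 0 calls.

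**Figure D3:**
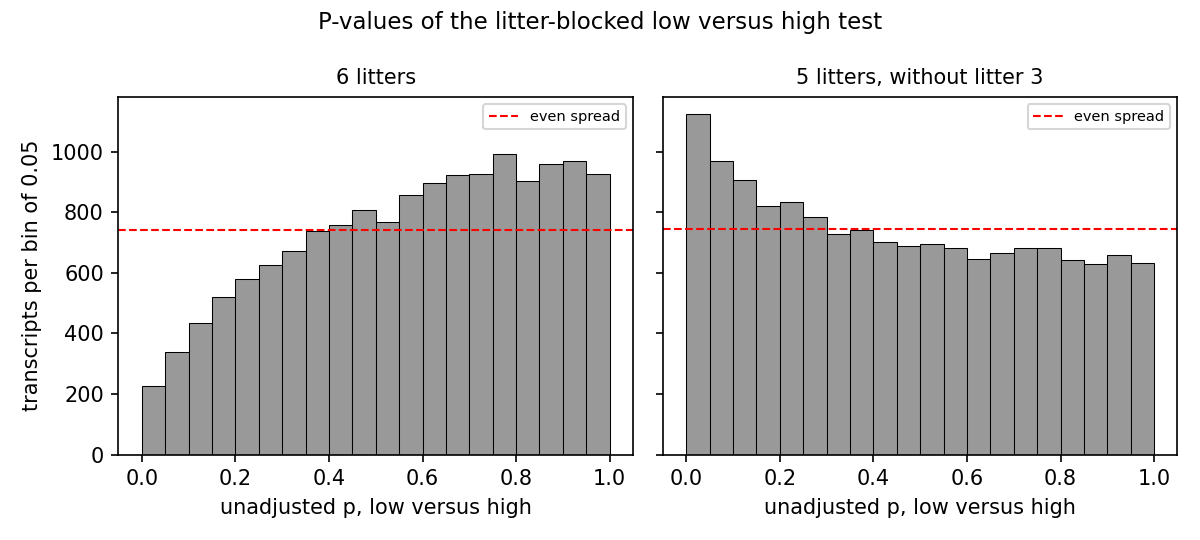
Number of transcripts (y axis) per bin of 0.05 of the unadjusted p for low versus high (x axis), from the test with the litter block. The left panel holds 6 litters and the right panel the 5 litters without litter 3, and the dashed line is an even spread. The lowest bin holds 225 transcripts on the left and 1126 on the right.

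The second comparison asked whether the difference between low and high gilts depended on the day of collection, 4 litters being from day 14 and 2 from day 15. In the edgeR quasi-likelihood test of the interaction, 0 of 14821 transcripts passed an adjusted p under 0.05, with a smallest adjusted p of 0.706, and 166 had an unadjusted p under 0.05. DESeq2 called 3. The median standard error of the difference between days was 0.38 on the log2 scale. In simulated counts the same test recovered 10.4% of the transcripts with a 2-fold and 83.3% of those with a 4-fold difference between days. Those counts were drawn independently for each transcript and held no outlying library, so recovery in the real libraries may differ. Littermates shared the day of collection, and day was not tested as a main effect.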

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

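The test without the most abundant transcripts, limma-voom with quality weights, the exchange with litter 1, the count of one direction in 5 litters and the test of litter 3 as the source of the missing small p-values were chosen after the results were seen; the thinning of libraries, the exchange with litter 6 and the other counts of arrangements were set down before. In 27 sets of 6 values (library measures, named transcripts and pair measures), 7 held a value far from the other 5, by Dixon's criterion at 95%, where chance would give about 1.35.

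The low library of litter 3 stood far from the other low libraries on 3 measures, and its pair on a further one. It had 233 transcripts more than 4-fold below the median of the other libraries, the next low library having 48. Its mean correlation with the other libraries was 0.950, the next being 0.970, and its 10 most abundant transcripts held 7.43% of reads, the next being 8.52%. The median absolute log2 difference between the littermates of litter 3 was 0.53, against at most 0.29 in the other litters. Depth does not account for this: after all libraries were thinned to 20809072 reads it still had 172 such transcripts, and the next highest library had 80. A few transcripts taking most of the reads do not account for it either, since its 10 most abundant held a smaller share than in any other library. Removing abundant transcripts could therefore show little. With the 100 most abundant transcripts of every library removed, 153 in all with 30.0% of its reads, levels were scaled by the remaining reads alone. The low library of litter 3 then had 231 transcripts more than 4-fold below the median of the others, and the next highest library had 80. Before their removal, on the same scale, it had 227. For litter labels exchanged with the low library of litter 6, the other litter with a weak pair correlation, the criterion was both crossed correlations over 0.1. It was not met, at -0.266 and 0.152. The labelled pairs, at 0.021 and 0.097, do not meet it either, so the criterion does not decide this exchange. For an exchange with the low library of litter 1 both crossed correlations were over 0.1, at 0.303 and 0.143. The low library of litter 1 correlated more with its own littermate, at 0.374, so that the exchange with litter 1 cannot be told apart from the labelled pairing. Such an exchange would bear on the pair and not on the distance of the library from all others. Other tissue in the sample, RNA quality and an unusual animal remain open, since no transcript was given a gene name and 5 other low libraries did not share the pattern.

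The high library of litter 1 stood apart from the other high libraries in its mean correlation with all libraries, 0.964 against 0.971 for the next. Its deviations correlated at 0.303 with those of the low library of litter 3.

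For ENSSSCT00000087297, the low library of litter 4, at 3.43 CPM, and the high library of litter 4, at 1.96 CPM, were each far above the other 5 of their group, whose highest values were 1.19 and 0.324 CPM.

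Other arrangements of the libraries cannot test the number of transcripts changed between low and high gilts, since the real count is 0 and any arrangement gives at least as many. This holds for the 32 of 32 exchanges of low and high within litters, where the highest other count was 1 for changed transcripts, 1 for transcripts higher in low gilts and 0 for lower ones, and for the 60 of 60 splits drawn from the 462 divisions of the 12 libraries into equal groups. Among these splits the highest count was 1459, from a split that put the high library of litter 1 and the low library of litter 3 on one side and their littermates on the other, with litters 2, 4, 5 and 6 kept whole. The real split parts 6 litters and this one 2. Litters kept whole are absorbed by the litter block, so its difference is estimated from litters 1 and 3 alone, and the cause of its count was not tested.

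Fewer transcripts than chance had an unadjusted p under 0.05 for low versus high in edgeR. With the litter block, limma-voom gave 251 and DESeq2 264, so the shortfall was not particular to edgeR. It was absent when libraries were weighted: limma-voom with quality weights per library gave 837 with all 6 litters, above the 741 expected by chance. Of the 32 exchanges within litters in edgeR, 30 gave at least the real 225, and the highest other was 2126. The lowest was 183 and another gave 218, so the real count was low but not the lowest. Counts under 741 thus also arose with exchanged labels, and the shortfall was not particular to the real ones. A candidate explanation is litter 3: without it the share at an unadjusted p under 0.05 was 7.55%, and without any other litter it was at most 1.70%. Leaving it out does not separate its spread from its direction. With low and high exchanged in litter 3 only and every library kept, the count was 1954. The median standard error was then 0.15, against 0.17 with the real labels. The direction of the difference in litter 3 therefore bears on the shortfall. Without the litter block and without the low library of litter 3, edgeR gave 255 of 14974. The 16 exchanges without litter 3 are too few for a share under 5%; the real count was 1126 and the highest other 1240, with 2 of 16 at least as large as the real one. For transcripts with 1 direction in 6 of 6 litters, 26 of 32 exchanges gave at least the real 255, and the highest other was 1241. Without litter 3, 3 of 16 exchanges, too few for a share under 5%, gave at least the real 1244 transcripts with 1 direction in 5 of 5 litters, and the highest other was 1479.

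For the dependence on day, the real count was 0, so that the 15 of 15 choices of 2 litters that gave at least as many were fixed in advance and test nothing; the highest other count was 1.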

How the results depend on the processing

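The fit to the rows with an ID, quality weights, counts left unrounded, the fit without the low library of litter 3 and all alternatives for variation between litters were added after seeing the data. The number of transcripts changed between low and high gilts was 0 under each alternative except DESeq2. DESeq2 with the litter block called 2, of which 0 were higher and 2 lower in low gilts, both on the filtered transcripts and on the 19407 rows with an ID; the cause was not tested. The fit without the replicate block was run only for low versus high in edgeR. Its count was 0, with 92 transcripts at an unadjusted p under 0.05, and among the results it covered the block changed no other call. Leaving out each litter in turn gave 0 calls for changed, higher and lower transcripts. At an unadjusted p under 0.05, edgeR without robust estimation gave 234 transcripts, limma-voom 251, limma-voom with quality weights 837, above the 741 expected by chance, no low-count filter 296 and limma-trend without a filter 523. The dependence on day gave 3 transcripts with DESeq2 and 2 without a low-count filter, and the cause was not tested; leaving out each litter in turn gave 0.

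The log2 fold changes of the 4 named transcripts kept their direction in every alternative that tested them, 24 for ENSSSCT00000047075 (-1.79 to -1.13), 21 for ENSSSCT00000054731 (-3.12 to -1.004), 24 for ENSSSCT00000071792 (0.60 to 0.93) and 18 for ENSSSCT00000087297 (0.37 to 1.25). The last and ENSSSCT00000054731 fell under the low-count filter in the remaining ones. ENSSSCT00000047075 and ENSSSCT00000054731 passed the threshold in 2 alternatives each, both with DESeq2, with adjusted p over all alternatives from 0.000444 to 1.00 and from 0.0186 to 1.00. The value nearest 0 came with a pseudocount of 1 for all but ENSSSCT00000071792, which follows from its construction, and without litter 6 for ENSSSCT00000071792.

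The number of transcripts differing between litters moved from 85 to 1601 with the DESeq2 likelihood ratio test and to 516 without a low-count filter; the cause was not tested. Leaving out each litter gave 7 to 1179, the highest without litter 3 and the lowest without litter 5, with 32 without litter 2 and 19 without litter 4. Tests of gene lists, camera with a preset or estimated correlation, fry and their alternatives, were not run because no ID was paired with a gene. Depth limits transcripts such as ENSSSCT00000054731, with as few as 2 reads in a library.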

Other observations

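The tests of variation between litters and the tests of row order against the p-values of contrasts were chosen after the results were seen; the test of row order against mean level was set down before.

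Transcript levels differed between litters. In the edgeR quasi-likelihood test of the litter terms, 85 of 14821 transcripts passed an adjusted p under 0.05 and 2641 had an unadjusted p under 0.05, where 741 would be expected by chance. The median log2 range over litters was 0.72 over all transcripts and 2.27 among the 85, which were selected for differing. Of 50 pairings of low with high libraries drawn from 720, 2 gave as many as 85, the real one included, or 4.00%. The other, which kept 2 true pairs, gave 172. With so few drawn, this share is weak evidence against chance pairing. At an unadjusted p under 0.05 that other pairing gave 3024, above the real 2641. Drawn pairings that kept 0 true pairs gave 100 to 1382, so counts over 741 also arose without any true pair. The count of 85 fell to 32 without litter 2, 19 without litter 4 and 7 without litter 5, and rose to 1179 without litter 3. With 6 litters, litters held a mean of 56.8% of the variance against 47.5% on average over all pairings. Of the 720 pairings, 43 gave as much (exact permutation p = 0.0597, one-sided). The highest share, 62.2%, came from the pairing that exchanged the low libraries of litters 1 and 3. Without litter 3 the share was 59.6% against 45.1% on average over all pairings. Of the 120 pairings, only the real one gave as much (exact permutation p = 0.00833, one-sided, the smallest possible). Litter 3 had the least similar littermates, at a correlation of 0.021, so leaving it out favours the real pairing. The smaller p therefore adds no independent support, and the same selection applies to the count of 1179. Shared genes, the sow and the litter's environment may each contribute, as may the day of collection, which differed for litters 4 and 5. The count of 1179 without litter 3 does not separate them. Any date or batch of processing that littermates shared was not tested and cannot be told apart from litter.

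The order of the deposited rows with an ID followed a litter contrast and not the iCrit contrast. In a DESeq2 model of group and litter on the reads of the 19407 rows, the Spearman rho between row position and the p-value of litter 6 against litter 1 was 1.00. It was at most 0.599 for the other litter contrasts and 0.125 for low against high. Mean level does not account for the order, with a rho of -0.300. A candidate explanation is that the rows were sorted by the p-value of the last litter term of such a model. At an adjusted p under 0.05, that contrast held 214 transcripts and low against high held 2. Which contrast the study used cannot be told from the order alone.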
